A study of Mus musculus with 15 samples.

How the data were processed

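RNA sequencing was measured in 15 libraries of eosinophils from 7 C57BL/6 wild-type mice. Per the series design text, the mice had been given 4-nitroquinoline 1-oxide (4-NQO), a carcinogen of the oral cavity and esophagus, and then its vehicle propylene glycol, a course that ended in a pre-cancer stage. Eosinophils, granulocytes of type 2 immunity, came from the lamina propria of esophagus and colon by immunomagnetic positive selection, and a further group is described as bone marrow-derived. The labels do not say whether that group was isolated from bone marrow or cultured from it. Per the labels' protocols, total RNA was amplified with the Ovation RNA-Seq System V2 and made into libraries with an NEB kit. The groups were 7 esophagus, 4 colon and 4 bone marrow libraries. Mice 5 to 8 gave all 3 tissues, and mice 1 to 3 an esophagus library alone. All F mice shared cage 1 and all M mice cage 2, so sex and cage are one split.

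The authors deposited one table of raw counts, as its title says, and every value in it is a whole number. It holds 26366 genes with symbol and versioned Ensembl identifier. The submitters' processing notes name limma 3.50.3 with no role. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Of the gene identifiers, 26299 (99.75%) matched GENCODE M21 by stable identifier, but 11 carried the same version and 26286 a higher one, so that release served for gene class, chromosome and exonic length and no coordinates are given. How reads shared between gene copies were counted is not stated, so values of paralogs, pseudogenes and Rn18s are uncertain. In the table, 32 symbols belong to more than 1 gene.

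Total counts ranged from 85677 to 612386 per library. A count of 0 allows up to 3 counts, which is 4.90 to 35 CPM of the library total. Intervals of shares are 95% Wilson intervals. For genes with 1 to 3 counts in a group, the ratio of pooled counts is given with an exact 95% interval. Intervals and floors cover counting error only, since amplified reads are not independent molecules. Levels are given as CPM, the depth-scaled counts of edgeR's cpm function, relative to all tested genes' counts times the scaling factor for tested genes and to the library total for others, and spreads are SDs over libraries. Fold changes against a group with 0 counts in every library are given as bounds, against a floor of 3 counts in each library.

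Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and other steps in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 10357, and scaled by TMM. The 3 tissue comparisons came from one edgeR quasi-likelihood fit with robust dispersion over all 15 libraries, with 12 residual degrees of freedom and no block. The common biological coefficient of variation was 0.817. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors (SE) are those of the log2 fold change, from the F statistic. Adjusted p-values of genes in the tissue comparisons and the interaction are from this edgeR test. The sex or cage difference was fitted with limma voom, with tissue as a term and mouse as a random block, and the tissue by sex interaction with an edgeR test of 2 degrees of freedom.

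For the count of genes shared by the comparisons against bone marrow, counts of all 15 libraries were simulated with no tissue difference in 20 draws. The real bone marrow libraries were also divided 2 and 2 in 6 ways. Samples of the same mouse are paired by the labels. Over all genes, the deviations of 12 same-mouse pairs from their group means correlated at -0.0198 to 0.0324, with a mean of 0.0174. The 36 other pairs gave -0.0623 to 0.0698, with a mean of -0.00576.

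In all, 37 gene lists were fixed: eosinophil surface and receptors, eosinophil granule proteins, granulocyte progenitor and eosinophil maturation, proliferation, activated tissue eosinophil, NF-kB targets, checkpoint and costimulation, antigen presentation class II and class I, chemokines, cytokines and growth factors, cytotoxic effectors, type I interferon response, hypoxia and glycolysis, oxidative phosphorylation, aryl hydrocarbon receptor pathway, matrix remodelling, lipid mediator synthesis, immediate early and heat shock, adhesion and migration, NADPH oxidase, and apoptosis regulators. The other lists hold markers of squamous epithelium, colon epithelium, tuft cells, fibroblasts, endothelium, muscle, macrophages, dendritic cells, neutrophils, monocytes, B and plasma cells, T and NK cells, mast cells and basophils, erythroid cells, and megakaryocytes and platelets. The 29 lists with at least 3 tested members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists and comparisons together, 87 tests in all. Camera was repeated with an estimated correlation, and fry tested whether a list's genes moved, on balance, one way.

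Genes named in the text follow a rule. Per tissue comparison, it takes up to 10 called genes per direction with the largest change, a mean of at least 20 CPM in the higher tissue and every library of one tissue above every library of the other, leaving out Gm, Rik, mt-, Rpl and Rps names. The rule adds Siglecf, Ccr3, Il5ra, Epx, Prg2 and Cd274 in each comparison. For a list described, it adds up to 2 risen and 2 fallen members, or the 2 members with the highest mean where none was called. It takes the 5 genes with the smallest p for sex or cage and 3 for the interaction, and up to 10 genes per direction shared by both comparisons with bone marrow. One gene that the rule takes is not reported here, and its place was not refilled. Groups, tests, lists, this rule and the alternatives were chosen before the data were examined, except the 2 alternatives named below as later choices.

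Alternatives were other scalings (RLE, upper quartile, library size), no filter, a stricter filter of at least 10 counts in at least 7 libraries, DESeq2, limma voom with sample quality weights, robust dispersion off, mouse as a fixed or a random block, sex as a covariate, fits of only 2 tissues or only mice 5 to 8, a test against a 2-fold change, a threshold of 0.01, removal of 120 mitochondrial, ribosomal protein and hemoglobin genes, and leaving out each library in turn. After the data were seen, 2 more were added: leaving out the 3 esophagus libraries of mice 1, 3 and 5 and the colon library of mouse 8, and removing 1457 genes with a purine or pyrimidine run of at least 50 bases. The tests were checked on simulated counts of 10357 genes. For esophagus against bone marrow, 11.6% of genes changed 4-fold and 73% of those changed 16-fold were found, with 4.08% of calls false. For colon against bone marrow these were 11.4%, 58.2% and 3.06%, and for esophagus against colon 14.4%, 72% and 4.43%. For sex or cage they were 32%, 86% and 9.23% in 1 draw, so the false share was above the 0.05 of the threshold. Libraries of a mouse were simulated as independent, so the effect of their correlation was not checked. The list test was simulated for esophagus against bone marrow at an unadjusted p under 0.05, with genes drawn independently. A list of 15 genes raised 2-fold was found in 10 of 10 draws, and 7 of 100 unchanged lists passed the same bound. Power after adjustment, or with correlated genes, was not simulated.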

Results

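The libraries profile gene counts of eosinophils from 3 sites of mice at a pre-cancer stage of esophageal carcinogenesis. The series is about effects of eosinophils against tumors in esophageal squamous cell carcinoma. Esophageal eosinophils were compared with bone marrow eosinophils, with colonic eosinophils standing as a second tissue population. There were 7 esophagus libraries (mice 1, 2, 5 and 6, F; mice 3, 7 and 8, M), and 4 libraries each of colon and bone marrow (mice 5 and 6, F; mice 7 and 8, M). All mice had the same treatment, and no untreated library is part of the series.

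Total counts were low in every library. In esophagus they were 141648, 371218, 85677, 88991, 202677, 227133 and 195611 for mice 1, 2, 3, 5, 6, 7 and 8. Colon libraries of mice 5, 6, 7 and 8 held 519668, 227179, 555689 and 612386 counts, and bone marrow libraries of the same mice 189336, 189060, 286166 and 246842. Between 6965 and 19981 genes were detected per esophagus library, 22284 to 25336 per colon library and 19020 to 22110 per bone marrow library. Spearman correlations across genes, which are not independent replicates, were 0.107 to 0.333 between esophagus libraries, 0.5 to 0.717 between colon libraries and 0.437 to 0.518 between bone marrow libraries. The colon library of mouse 8 stood apart, with 7.52% mitochondrial counts (95% interval 7.45 to 7.58) and 1.36% ribosomal protein counts (1.34 to 1.39). The other colon libraries had 0.298% to 1.0% and 0.232% to 0.241%. In esophagus, mitochondrial counts were 3.87% in mouse 1 (3.77 to 3.97) and 2.84% in mouse 3 (2.73 to 2.95), and 0.301% to 0.441% in the other 5 libraries.

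Genes for smell receptors held as many counts per length as other coding genes. Olfactory and vomeronasal receptor genes (1431 genes), which act in sensory neurons, had 0.957 to 7.86 counts per exonic kilobase per library, and 18000 other autosomal coding genes 0.627 to 4.95. These densities, and the pseudogene and X-linked ratios below, leave out the 1% of genes with the most counts in each library. The gene numbers are those before this cut, and densities without it were not computed. The ratio of the 2 was 1.25 to 2.12, above 1 in all 15 libraries. Pseudogenes had 1.03 to 1.33 times the counts per kilobase of coding genes. Across genes, counts followed exonic length, with Spearman correlations of 0.372 to 0.848. Counts per kilobase of X-linked genes of every type were set against those of autosomal coding genes, the receptors among them. This gave 1.10 ± 0.0537 (SD, n = 4 mice) in F and 0.581 ± 0.0484 (SD, n = 3 mice) in M mice, a ratio of 0.528. The 2 sides differ in gene type, so the levels themselves do not compare like genes. An exact two-sided permutation test gave p = 0.0571, the smallest that the 35 splits of the mice allow. The split held within each tissue, with means of 1.13 in F and 0.580 in M in esophagus, 1.15 and 0.554 in colon, and 1.03 and 0.653 in bone marrow.

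**Figure D1:**
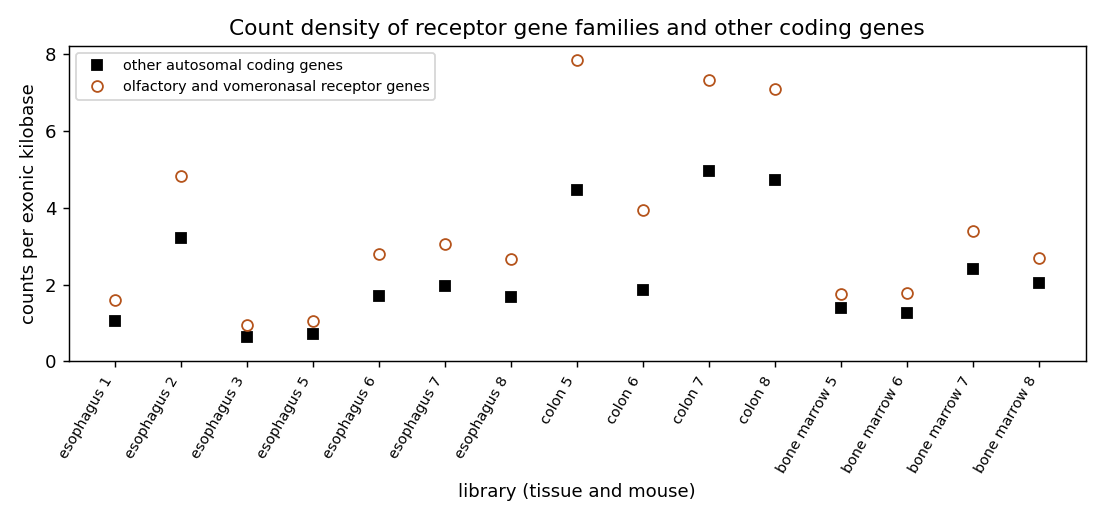
Counts per exonic kilobase (y axis) in each of the 15 libraries (x axis), for olfactory and vomeronasal receptor genes (open circles) and other autosomal coding genes (black squares). The receptor genes lie above the coding genes in every library, by 1.25 to 2.12 times. The 1% of genes with the most counts in each library is left out.

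**Figure D2:**
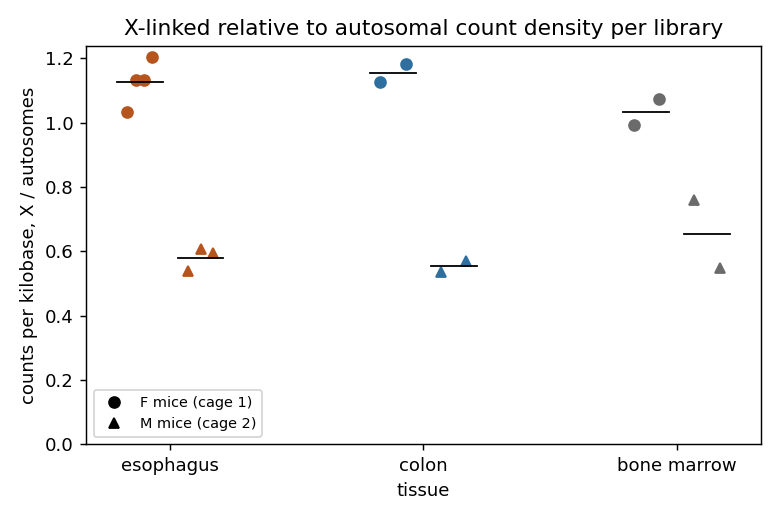
Counts per kilobase of X-linked genes of every type relative to autosomal coding genes (y axis) by tissue (x axis). Circles are libraries of F mice in cage 1, triangles those of M mice in cage 2, and lines lie at the means. F libraries lie between 0.993 and 1.21, and M libraries between 0.537 and 0.758. The 1% of genes with the most counts in each library is left out.

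Genes that define eosinophils were near the floor of detection. Epx, the eosinophil peroxidase, had 0 counts in all 7 esophagus libraries, which allows up to 8.08 to 35 CPM, 0 to 9 counts in colon and 2 to 5 in bone marrow. Prg2, the major basic protein, had 10 counts in the esophagus library of mouse 6, 1 in the colon library of mouse 7 and 0 in the other 13 libraries. Siglecf, a surface lectin used to sort mouse eosinophils, had 0 to 9 counts in esophagus, 2 to 13 in colon and 0 to 6 in bone marrow. Il5ra, the receptor for interleukin 5, had 0 to 33, 5 to 23 and 4 to 8. None of these 4 passed the filter for testing. Ccr3, the eotaxin receptor, had 101 ± 55.2 CPM (SD, n = 7) in esophagus, 67.6 ± 19.5 (n = 4) in colon and 44.4 ± 36.6 (n = 4) in bone marrow, and Cd274, which encodes PD-L1, had 42.2 ± 70.2, 53.0 ± 16.3 and 110 ± 77.5 CPM. For Ccr3 the log2 differences were 1.22 (SE 0.94) for esophagus against bone marrow, 0.64 (SE 1.01) for colon against bone marrow and 0.57 (SE 0.88) for esophagus against colon. For Cd274 they were -1.35 (SE 0.94), -1.03 (SE 1.06) and -0.32 (SE 0.94). Leaving out 1 library at a time gave Cd274 differences of -2.80 to -0.93, -1.36 to -0.52 and -1.77 to -0.08. No Ccr3 or Cd274 difference passed edgeR's test, with adjusted p of 0.999 for esophagus against bone marrow and 1.0 for the others.

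The esophagus libraries had far lower counts of a set of genes that were abundant in the bone marrow libraries. Itgam (ENSMUSG00000030786.19), which encodes the integrin CD11b, fell from 24030 ± 9877 CPM (SD, n = 4) in bone marrow to 99 ± 64.1 (n = 7) in esophagus, a log2 fold change of -7.94 (SE 0.45, adjusted p = 9.08e-25). Trim12c (ENSMUSG00000057143.16), of the TRIM family with near paralogs, fell from 27440 ± 21170 to 184 ± 173 CPM (-7.25, SE 0.91, adjusted p = 0.000901). Ddx23 (ENSMUSG00000003360.16), an RNA helicase of the spliceosome, fell from 7936 ± 7009 to 40.7 ± 33.0 CPM, and Tor1aip1 (ENSMUSG00000026466.17), of the inner nuclear membrane, from 7578 ± 7788 to 45.5 ± 40.8. Their log2 fold changes were -7.58 (SE 1.0, adjusted p = 0.00139) and -7.34 (SE 0.94, adjusted p = 0.00105), or -6.91 and -6.49 without bone marrow of mouse 6.

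Among the other genes that fell in esophagus, several were near 0 there. AA465934 (ENSMUSG00000093483.2), a noncoding transcript, had 0 counts in all 7 esophagus libraries against 588 ± 457 CPM in bone marrow, at least 26.9-fold lower (adjusted p = 3.64e-14). Tbata (ENSMUSG00000020096.22) had 2 counts over the esophagus libraries and 793 over bone marrow, where its mean was 1582 ± 1360 CPM. After scaling, this was a ratio of 714 (exact interval 197 to 5907, adjusted p = 0.000311), with 1300 or 1200 without esophagus of mouse 3 or 7, which held 1 count each, and 462 without bone marrow of mouse 6. Bco1 (ENSMUSG00000031845.17), which cleaves beta-carotene, had 3 counts and 385, with 813 ± 1077 CPM in bone marrow and a ratio of 231 (78.5 to 1126, adjusted p = 4.80e-13). Its 3 counts were in esophagus of mouse 8, and 263 of the 385 in bone marrow of mouse 6, without which the ratio was 89.2. Amt (ENSMUSG00000032607.13), of the glycine cleavage system, had 2 counts and 167, with 322 ± 230 CPM and a ratio of 150 (41.0 to 1252, adjusted p = 1.48e-07), or 274 without esophagus of mouse 3. Gapdh-ps16 (ENSMUSG00000078967.6), a pseudogene whose reads may be shared with Gapdh, had 0 counts in esophagus against 77.2 ± 24.4 CPM, at least 3.53-fold lower (adjusted p = 0.00578, and 0.118 with mouse as a block). In each of these 9 genes, every esophagus library lay below every bone marrow library, which the naming rule requires.

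In total, edgeR called 2 genes higher and 84 lower in esophagus than in bone marrow, with 71 and 404 at an unadjusted p under 0.05 where chance gives 518 in all. The median log2 fold change of all tested genes was -0.18 with TMM and 0.21 by library size alone, so folds of this size depend on the scaling. Of the lower genes, 61 met every condition for being named. Neither higher gene did, so both were chosen after their values were seen. Tpst1 (ENSMUSG00000034118.16), which sulfates tyrosines of proteins, had 85.3 ± 86.7 CPM in esophagus and 0 counts in bone marrow, at least 4.05-fold higher (adjusted p = 0.0159). Ddx50 (ENSMUSG00000020076.8), a nucleolar RNA helicase, had 702 ± 482 against 194 ± 74.2 CPM (1.84, SE 0.47, adjusted p = 0.0182). Their adjusted p was 0.277 and 0.227 with mouse as a block. The Tpst1 call was lost without the bone marrow library of mouse 5, 6, 7 or 8 (0.0859, 0.0856, 0.0805, 0.0821), and without esophagus of mouse 1, 2, 3 or 7 the gene did not pass the filter. Ddx50 lost it without esophagus of mouse 1, 3 or 7 (0.0781, 0.0713, 0.0514) or bone marrow of mouse 5, 6 or 8 (0.151, 0.0895, 0.107). The higher count was 0 without esophagus of mouse 3, 1 without that of mouse 1, 5 without colon of mouse 6 or bone marrow of mouse 6 or 8, 6 without colon of mouse 7, and 7 without colon of mouse 5 or 8 or bone marrow of mouse 7. It was 3 with mouse as a block, none of them Tpst1 or Ddx50. Without genes that hold a purine or pyrimidine run, as 45 of the 84 do, 39 genes were lower.

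**Figure D3:**
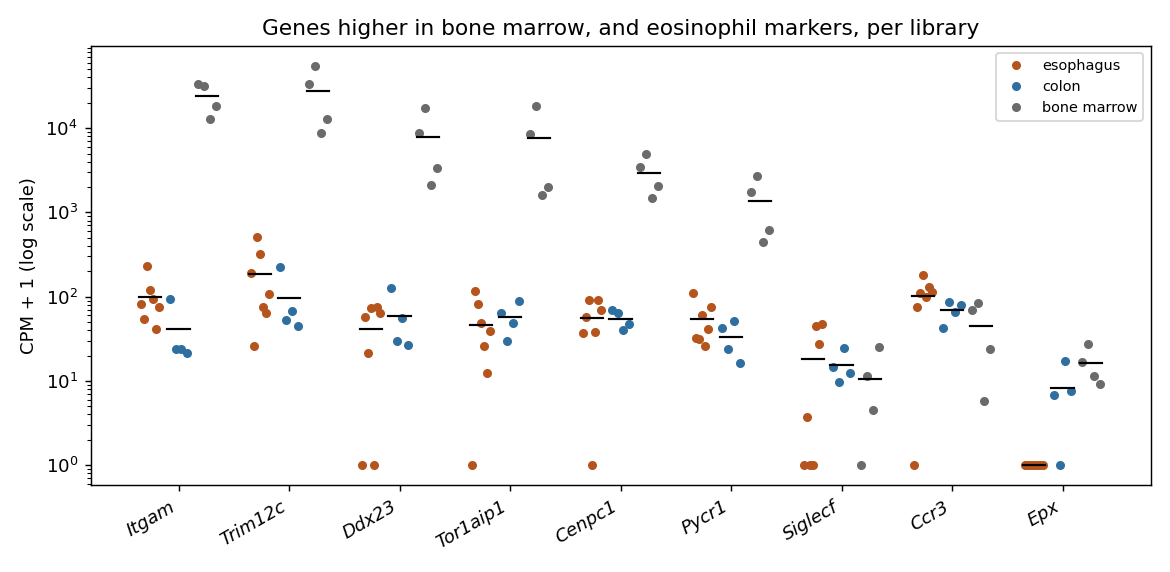
CPM plus 1 (y axis, log scale) of 9 genes in each library (points) by tissue, with lines at the means: Itgam, Trim12c, Ddx23, Tor1aip1, Cenpc1, Pycr1, Siglecf, Ccr3 and Epx. Itgam lies at 12980 CPM or more in each bone marrow library and at 232 or less in each esophagus and colon library.

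The colon libraries also had low counts of genes abundant in the bone marrow libraries. Itgam was at 39.8 ± 35.6 CPM (SD, n = 4) in colon (-9.20, SE 0.61, adjusted p = 1.03e-20) and Trim12c at 96.0 ± 85.2 (-8.14, SE 1.21, adjusted p = 0.00755). Ddx23 fell to 58.5 ± 46.2 CPM (-7.05, SE 1.24, adjusted p = 0.0261) and Tor1aip1 to 56.7 ± 24.6 (-7.03, SE 1.17, adjusted p = 0.0177). Cenpc1 (ENSMUSG00000029253.13), a centromere protein, fell from 2973 ± 1535 to 54.0 ± 14.0 CPM (-5.77, SE 0.54, adjusted p = 1.16e-16), and Pycr1 (ENSMUSG00000025140.16), an enzyme of proline synthesis, from 1376 ± 1045 to 32.5 ± 16.2 (-5.35, SE 0.61, adjusted p = 6.14e-12). Fhl3 (ENSMUSG00000032643.13), a LIM domain protein, fell from 541 ± 498 to 4.52 ± 2.61 CPM (-6.77, SE 1.27, adjusted p = 0.00409), Tbata to 16.5 ± 21.4 (-6.54, SE 1.14, adjusted p = 0.0171) and AA465934 to 10.9 ± 7.38 (-5.74, SE 0.90, adjusted p = 3.38e-06). Without bone marrow of mouse 6, log2 fold changes were -7.54 for Trim12c, -6.30 for Ddx23, -6.10 for Tor1aip1, -6.0 for Fhl3, -5.83 for Tbata and -5.11 for AA465934. Without colon of mouse 5 they were -10.0 for Itgam, -8.97 for Trim12c, -7.72 for Ddx23 and -8.18 for Tbata.

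Every colon library lay below every bone marrow library in these 9 genes, again by the naming rule. No gene was called higher in colon by edgeR, with 53 at an unadjusted p under 0.05, 0 called by DESeq2, 5 by limma voom with quality weights and 1 with mouse as a block. In colon, 45 genes were lower (166 unadjusted), of which 38 met the conditions, and the median log2 fold change of all genes was 0.02, or 0.23 by library size. A mouse block gave 79 lower genes, without the bone marrow library of mouse 7 there were 74, and without purine-run genes, which take away 26 of the 45, there were 11. Leaving out colon of mouse 5, 6 or 7 gave 18, 16 or 19 higher genes, and leaving out bone marrow of mouse 5, 6, 7 or 8 gave 2, 4, 6 or 2. Without colon of mouse 8, the calls of Ddx23 (0.0985) and Tor1aip1 (0.0585) were lost, as was that of Ddx23 without bone marrow of mouse 5 (0.0536).

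Genes lower in both tissues than in bone marrow numbered 42, and 31 of them met the naming conditions in both. The largest were Itgam, Trim12c, Ddx23, Tor1aip1, Tbata and AA465934, with the values above. They were followed by Cenpc1, with a log2 fold change of -5.73 in esophagus (adjusted p = 8.31e-24), Cdk15 (ENSMUSG00000026023.17), a cyclin-dependent kinase, and Dppa2 (ENSMUSG00000072419.6), a gene of pluripotent cells. Cdk15 had 6.57 ± 9.39 CPM in esophagus, 8.04 ± 8.27 in colon and 342 ± 314 in bone marrow (-5.33, SE 0.92, adjusted p = 1.69e-05, and -5.27, SE 1.11, adjusted p = 0.00241). Dppa2 had 14.1 ± 30.1, 24.2 ± 12.4 and 887 ± 907 CPM (-5.81, SE 0.94, adjusted p = 0.00213, and -5.15, SE 1.10, adjusted p = 0.0480). Leaving out bone marrow of mouse 6 gave -4.64 and -4.47 for Cdk15 and -4.94 and -4.17 for Dppa2. Cdk15 was at -5.97 in esophagus without that of mouse 2 and -6.18 in colon without that of mouse 5, and Dppa2 at -7.63 in esophagus without that of mouse 8. Under a mouse block, adjusted p for Dppa2 was 0.149 and 0.193. Its colon call was lost without esophagus of mouse 1, 2, 3, 5 or 6 (0.0533, 0.0897, 0.0845, 0.0679, 0.0612), and that of Cdk15 without bone marrow of mouse 6 (0.223). No gene was called higher in both by edgeR, DESeq2 or limma voom with quality weights, and the 2 comparisons had 71 and 53 higher genes at an unadjusted p under 0.05.

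With mouse as a random block in limma voom, instead of the fixed term in edgeR used elsewhere here, many of these calls were lost. It gave 77 lower genes in esophagus, 41 of them among the 84, and 14 in colon, 7 of them among the 45. In esophagus, adjusted p was 0.991 for Itgam (log2 fold change -7.40), 0.9945 for Trim12c (-6.50), 0.964 for Ddx23 (-11.5), 0.884 for Tor1aip1 (-6.78), 0.207 for Tbata (-7.22), 0.387 for Cenpc1 (-5.33) and 0.0579 for Dppa2 (-5.58). AA465934, Bco1, Amt, Gapdh-ps16 and Cdk15 kept their calls there, and Tpst1 and Ddx50 were at 0.220 and 0.538. In colon, Itgam (-8.1), Trim12c (-1.91), Ddx23 (-11.5), Tor1aip1 (-6.09), Tbata (-6.57) and Cenpc1 (-5.19) were at 1.0, and Pycr1, Fhl3, Dppa2, AA465934 and Cdk15 at 0.737, 0.377, 0.385, 0.0726 and 0.0641. Tpst1 and Ddx50 stayed higher in esophagus (3.61 and 1.07), and all the other genes named here stayed lower in tissue. Why the calls were lost was not tested.

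Both comparisons share the bone marrow libraries. Simulated unchanged groups, with the bone marrow counts simulated too, gave 0 shared lower genes in each of 20 draws. Outlying values of the real bone marrow libraries were thus not carried into the draws. Independent lists of these lengths would share 0.365. With the bone marrow libraries divided between the comparisons, 22 to 56 genes were lower in both (median 42.5). Over all tested genes, the log2 fold changes correlated at 0.631 (covariance 0.489), while simulated unchanged groups gave 0.585 (range 0.562 to 0.602, so the observed correlation was above all 20 draws) and a covariance of 0.506 (range 0.476 to 0.531). Divided libraries gave correlations of 0.227 to 0.290 and covariances of 0.262 to 0.319. The covariance was thus -0.0171 from the simulated one, no more than the spread of the draws. The shared count was 67 with mouse as a block, 37 of them among the 42, 69 without bone marrow of mouse 7, and 11 without purine-run genes.

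Genes of antigen presentation on MHC class II had higher counts in the esophagus than in the colon libraries. Cd74 (ENSMUSG00000024610.16), the invariant chain, rose from 33.2 ± 34.5 CPM (SD, n = 4) in colon to 412 ± 281 (n = 7) in esophagus, a log2 fold change of 3.56 (SE 0.63, adjusted p = 0.000650), or 4.51 without colon of mouse 8. H2-Ab1 (ENSMUSG00000073421.7), a class II beta chain, rose from 31.6 ± 23.5 to 305 ± 191 CPM (3.21, SE 0.72, adjusted p = 0.0356). Rn18s (ENSMUSG00000119584.1), the 18S ribosomal RNA, rose from 3064 ± 682 to 9520 ± 6505 CPM (1.64, SE 0.37, adjusted p = 0.0360). All esophagus libraries lay above all colon libraries for these 3 genes, as the naming rule requires. Mouse as a fixed block gave adjusted p of 0.197 for Cd74, 0.00721 for H2-Ab1 and 0.789 for Rn18s, and as a random block 0.196, 0.196 and 1.00e-08, so no gene of the 3 kept its call under both. The 2 class II genes kept their calls under all 3 other scalings, and Rn18s was at 0.438 with library size alone.

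The other 6 called genes were outside the naming rule and were chosen after their values were seen. H2-Ea (ENSMUSG00000036322.12), a class II alpha chain locus listed as a polymorphic pseudogene, rose from 5.47 ± 6.49 to 218 ± 240 CPM (5.02, SE 1.11, adjusted p = 0.0360; 4.37 without esophagus of mouse 5 and 5.62 without colon of mouse 8), and Actb (ENSMUSG00000029580.15), beta-actin, from 44.6 ± 8.05 to 419 ± 444 (3.20, SE 0.62, adjusted p = 0.00597). S100a4 (ENSMUSG00000001020.9), a calcium-binding protein, had 1 count over colon and 89 over esophagus, a ratio of 114 after scaling (exact interval 20 to 4566, adjusted p = 0.0498), or 49.4 without esophagus of mouse 3. Its 1 colon count was in mouse 7. Gm15772 (ENSMUSG00000062353.7), a processed pseudogene, rose from 6.16 ± 4.48 to 177 ± 172 CPM (4.67, SE 1.11, adjusted p = 0.0498). Tmem30b (ENSMUSG00000034435.7) fell from 236 ± 390 CPM in colon to 11.9 ± 23.0 in esophagus (-4.16, SE 0.92, adjusted p = 0.0356), with 322 of its colon counts in the library of mouse 8 and 8 to 24 in the others. Btbd35f11 (ENSMUSG00000094558.2) had 0 counts in esophagus against 80.1 ± 70.3 CPM in colon, at least 3.66-fold lower (adjusted p = 0.0498). A mouse block gave adjusted p of 0.270 for H2-Ea, 0.340 for Actb and S100a4, 0.532 for Gm15772, 0.789 for Tmem30b and 0.509 for Btbd35f11, and a random mouse block 0.203 to 0.299 for these 6.

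EdgeR thus called 7 genes higher and 2 lower in esophagus than in colon (60 and 215 unadjusted). Calls were 8 and 1 with RLE and 6 and 3 with upper-quartile scaling, and with mouse as a block 2 and 2, of which 1 higher gene, H2-Ab1, and 0 lower genes were shared. A random mouse block gave 1 higher gene, Rn18s, and 2 lower, 0 of them shared. The median log2 fold change of all genes was -0.21, or 0.01 with RLE. Leaving out the 3 smallest esophagus libraries and colon of mouse 8 together left 0 and 0 calls by edgeR, with Cd74 at 3.51 (adjusted p = 0.0550) and H2-Ab1 at 3.35 (0.0716). DESeq2 called 15 and 0. Without esophagus of mouse 1, 3, 5 or 7 the higher count was 3, 1, 2 or 3, and without bone marrow of mouse 6, 7 or 8 it was 12, 14 or 14. The lower count was 0 without esophagus of mouse 1, 3, 5 or 6, 1 without that of mouse 2 or 7, 17, 22, 18 or 4 without colon of mouse 5, 6, 7 or 8, and 12, 14, 15 or 18 without bone marrow of mouse 5, 6, 7 or 8.

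Single libraries decided most of these calls. The H2-Ab1 call was lost without esophagus of mouse 3, 5 or 8 (0.208, 0.15, 0.0593) or colon of mouse 5, 6 or 7 (0.0694, 0.0962, 0.129). For Rn18s, leaving out any 1 esophagus library gave 0.206 to 0.806, and colon of mouse 5, 6 or 7 gave 0.187, 0.214 and 0.105. Actb was lost without esophagus of mouse 1 or 3 (0.0843, 0.2), and S100a4 without esophagus of mouse 1 (0.0709) or colon of mouse 5, 6 or 8 (0.0876, 0.0577, 0.130), and did not pass the filter without esophagus of mouse 2, 3, 5, 7 or 8. H2-Ea was lost without esophagus of mouse 1, 3, 5, 6 or 7 (0.261, 0.406, 0.309, 0.0701, 0.0897), and Tmem30b without that of mouse 1, 3, 5, 6 or 8 (0.261, 0.406, 0.257, 0.0701, 0.0638), and did not pass the filter without esophagus of mouse 2 or 7 or colon of mouse 8. Btbd35f11 was lost without any 1 esophagus library (0.0824 to 0.406) or colon of mouse 6 (0.117). Gm15772 was lost without any esophagus library but that of mouse 8 (0.0551 to 0.415) or any colon library (0.0705 to 0.238). The Cd74 call held without any 1 library.

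As a group, the 5 tested members of the class II list (of 10 in the table) were higher in esophagus than in colon, with a median log2 fold change of 2.81 (camera, adjusted p = 1.04e-06). With an estimated correlation the adjusted p was 0.00896, and fry gave 0.0998. Camera's call held under every alternative on which it was run and without any 1 library, and without the 4 libraries above the adjusted p was 0.000135. Cd74 and H2-Ab1 rose, and 4 members rose adjusted over the list alone. H2-Aa, a class II alpha chain, had 328 ± 319 CPM in esophagus and 45.2 ± 14.3 in colon, and H2-Eb1, a second beta chain, 123 ± 136 and 31.4 ± 19.7 (adjusted p = 0.0602 and 1.0). H2-Aa was called with RLE, upper-quartile and library size scaling (0.0166, 0.0443, 0.00816), and without esophagus of mouse 2 (0.0189) or bone marrow of mouse 6, 7 or 8 (0.0474, 0.0332, 0.0339). Ciita, the transactivator of class II genes, had 53.9 ± 54.3 CPM in esophagus and 99.3 ± 17.2 in colon (adjusted p = 1.0). The list was also higher in esophagus than in bone marrow, with a median of 1.2 (camera, adjusted p = 0.0341). With an estimated correlation the adjusted p was 0.158. There, 0 members were called over all genes (edgeR) and 2 rose adjusted over the list alone. The log2 differences were 1.2 for Cd74 (adjusted p = 0.903; 0.92 to 1.85 without 1 library), 2.07 for H2-Ab1 (0.203) and 1.91 for H2-Aa (0.281). That list call was lost with RLE, upper-quartile and library size scaling (0.0999, 0.0626, 0.0913), with no filter (0.440), without the 4 libraries (0.293), and without esophagus of mouse 1, 3, 5 or 8 (0.0860, 0.179, 0.0665, 0.0729), while library size scaling called H2-Aa (0.0282) and H2-Ab1 (0.0161). In colon against bone marrow the list had an adjusted p of 0.135 (median -1.04, 1 member fell adjusted over the list alone). Cd74 was at -2.35 (adjusted p = 0.0655), or -3.34 to -1.59 without 1 library. It was called without colon of mouse 8 (0.00371) or bone marrow of mouse 5, 7 or 8 (0.0397, 0.0454, 0.0264).

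**Figure D4:**
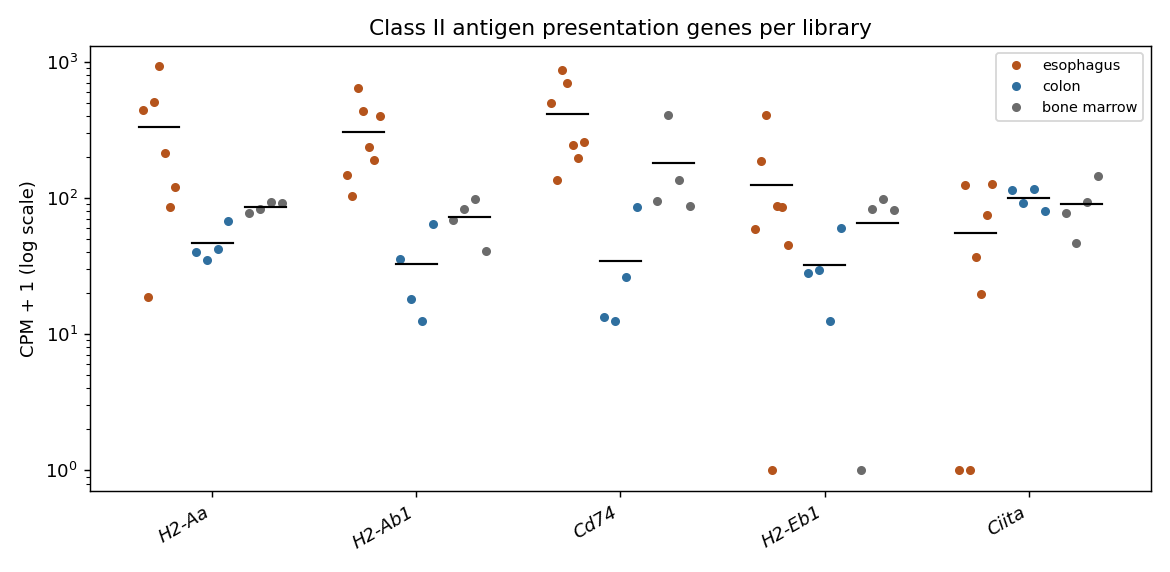
CPM plus 1 (y axis, log scale) of the 5 tested class II antigen presentation genes in each library (points) by tissue, with lines at the means. Cd74 had means of 412 CPM in esophagus, 33.2 in colon and 179 in bone marrow, and Ciita means of 53.9, 99.3 and 89.0 CPM.

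Cytokine and growth factor genes were higher as a group in esophagus than in colon, with a median log2 fold change of 0.74 over 10 tested members of 22 (camera, adjusted p = 0.0129). With an estimated correlation the adjusted p was 0.157, and fry gave 0.972. No member passed edgeR's test over all genes or adjusted over the list alone. The 2 most abundant members were Tgfa, an EGF receptor ligand, at 122 CPM in esophagus and 67.2 in colon, and Il1b, interleukin 1 beta, at 121 and 26.1. The call was lost with no filter, where 22 members were tested (0.724), without the 4 libraries (0.268) and without esophagus of mouse 5 (0.0665). Genes of hypoxia and glycolysis had a median of 0.64 over 16 tested members of 23 (camera, adjusted p = 0.0215). With an estimated correlation the adjusted p was 0.157, fry gave 0.602, and with mouse as a block camera gave 0.182. Of the members, 0 rose over all genes by edgeR and 1 rose adjusted over the list alone. Gapdh and Pfkl, enzymes of glycolysis, had 259 and 140 CPM in esophagus and 45.4 and 45.6 in colon. The call was lost with RLE and library size scaling (0.0751, 0.0871), with no filter (0.213), with quality weights (0.171), in mice 5 to 8 (0.359), without the 4 libraries (0.894), and without esophagus of mouse 1, 3 or 5 (0.154, 0.297, 0.117) or colon of mouse 5 or 6 (0.0513, 0.0781). The share of Rn18s counts moved with these groups, from 0.182% to 0.269% in colon to 0.323% to 2.61% in esophagus.

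No list was called in colon against bone marrow by camera, with 1 called with quality weights and 3 with mouse as a block. Several lists had single members that fell in tissue against bone marrow. In the eosinophil surface list (9 tested of 17), Itgam fell in both tissues and 2 members fell adjusted over the list alone in each, with list adjusted p of 0.761 in esophagus and in colon against bone marrow and 0.895 for esophagus against colon, where 1 member rose adjusted over the list alone. With mouse as a block the 2 comparisons with bone marrow were at 0.00149 and 0.000432, lower in tissue. Among endothelial markers (5 of 11), Pecam1, which encodes CD31 and is also present on leukocytes, fell from 1515 ± 701 CPM to 30.9 ± 27.4 in esophagus (-5.49, SE 0.50, adjusted p = 5.46e-16) and 65.7 ± 20.2 in colon (-4.51, SE 0.59, adjusted p = 1.82e-08, and 0.0842 with a random mouse block), and 1 member fell adjusted over the list alone in each. The list was at 0.761, 0.309 and 0.895, in the order esophagus against bone marrow, colon against bone marrow and esophagus against colon, with 0.0227 for colon against bone marrow with mouse as a block. Among B and plasma cell markers (5 of 16), Ebf1, a transcription factor of B cells, fell from 1194 ± 712 CPM to 86.7 ± 82.6 in esophagus (-3.72, SE 0.54, adjusted p = 1.21e-05) and 131 ± 27.0 in colon (-3.18, SE 0.65, adjusted p = 0.00676; 0.0867 and 0.101 with a random mouse block), 1 member fell adjusted over the list alone in each, and the list was at 0.761, 0.343 and 0.977. Of mast cell and basophil markers (3 of 11), Cyp11a1, a steroid-synthesis enzyme, fell from 6382 ± 4236 to 51.4 ± 78.7 CPM in esophagus (-6.88, SE 1.19, adjusted p = 0.0123, and 0.0517 and 0.937 with mouse as a fixed and a random block), and was at -7.84 without esophagus of mouse 7. That list was at 0.895, 0.907 and 0.844, and 1 member fell adjusted over the list alone in esophagus and 1 in colon against bone marrow. With mouse as a block it was at 0.00150 and 3.60e-05 in the comparisons with bone marrow.

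The remaining tested lists had no call by camera and no member called over all genes by edgeR. Their adjusted p-values follow for esophagus against bone marrow, colon against bone marrow and esophagus against colon. Lists of eosinophil biology were at 0.343, 0.408 and 0.895 for granulocyte progenitor and maturation genes, 0.901, 0.971 and 0.895 for proliferation, and 0.895, 0.702 and 0.899 for activated tissue eosinophil genes. Immune lists were at 0.702, 0.309 and 0.0730 for NF-kB targets, 0.895, 0.761 and 0.575 for checkpoint genes, 0.343, 0.977 and 0.177 for class I presentation, 0.343, 0.889 and 0.135 for chemokines, and 0.901, 0.901 and 0.982 for the type I interferon response. Oxidative phosphorylation was at 0.761, 0.187 and 0.648, the aryl hydrocarbon receptor pathway at 0.520, 0.759 and 0.793, matrix remodelling at 0.911, 0.899 and 0.901, and lipid mediator synthesis at 0.907, 0.520 and 0.648. Immediate early and heat shock genes were at 0.343, 0.793 and 0.0730, adhesion genes at 0.901, 0.939 and 0.841, and apoptosis regulators at 0.641, 0.554 and 0.977. Marker lists were at 0.474, 0.575 and 0.885 for squamous epithelium, 0.648, 0.977 and 0.554 for colon epithelium, 0.895, 0.909 and 0.761 for fibroblasts, and 0.308, 0.273 and 0.899 for macrophages. Dendritic cell markers were at 0.899, 0.899 and 0.956, monocyte markers at 0.135, 0.520 and 0.308, and T and NK cell markers at 0.885, 0.343 and 0.135. In esophagus against colon, 2 NF-kB targets, 1 chemokine and 1 activated eosinophil gene rose and 1 oxidative phosphorylation gene fell adjusted over the list alone, as 1 monocyte marker rose in esophagus against bone marrow. In 22 of the 87 tests, 0 of them called, the median, the mean and the test differed in sign. Fewer than 3 members passed the filter for 8 lists, which were not tested: eosinophil granule proteins (0 of 8), cytotoxic effectors (2 of 11), NADPH oxidase (1 of 7), tuft cells (2 of 11), muscle (2 of 12), neutrophils (2 of 13), erythroid cells (2 of 11) and megakaryocytes (2 of 10).

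Between F mice of cage 1 and M mice of cage 2, the 5 genes with the smallest p were ones abundant in bone marrow. With limma and mouse as a random block, Tor1aip1 was lower in M by a log2 difference of -2.80 (adjusted p = 1.26e-11; -3.46 to -2.33 without 1 library). Its means were 13370 CPM in F and 1789 in M bone marrow libraries (n = 2 each). Trim12c was at -2.0 (7.48e-10; 44010 and 10860 CPM in bone marrow), Itgam at -1.06 (2.00e-09; 32340 and 15720), Trerf1 (ENSMUSG00000064043.16), a transcription factor, at -2.11 (4.07e-08; 3707 and 884) and Rsu1 (ENSMUSG00000026727.11), a Ras suppressor, at -3.44 (4.07e-08; 10470 and 1059). In esophagus the means in F and M were 47.2 and 43.2 CPM for Tor1aip1, 153 and 224 for Trim12c, 86.5 and 116 for Itgam, 149 and 84.3 for Trerf1 and 86.6 and 133 for Rsu1. In colon they were 46.1 and 67.3 CPM for Tor1aip1, 137 and 54.8 for Trim12c, 57.9 and 21.6 for Itgam, 129 and 109 for Trerf1 and 94.6 and 135 for Rsu1, so Tor1aip1 and Rsu1 were higher in M there. In the esophagus libraries alone the difference was 0.53 for Trim12c, 0.38 for Itgam and 0.59 for Rsu1, the opposite direction. The fit takes 1 difference for all tissues, which these means do not show. Its p-values thus do not describe a difference shared by the tissues.

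In total 51 genes were called, 7 higher and 44 lower in M (206 unadjusted), of which 32 of the lower ones were also higher in bone marrow than in a tissue, and 4 were Y-linked and 4 X-linked. The median log2 difference was -1.09 over 306 X-linked genes, 92.2% of which were lower in M, -0.04 over 10011 autosomal genes and 3.71 over 12 Y-linked genes. EdgeR without the mouse block, a change of both tool and block, called 10 genes, none of the 5 named (adjusted p = 1.0 each), and in esophagus alone 3. Without the block, edgeR's log2 differences were smaller, at -0.80 for Tor1aip1, -0.65 for Trim12c, -0.49 for Itgam, -1.0 for Trerf1 and -0.35 for Rsu1. The count of 51 was 33 without bone marrow of mouse 5, 21 without that of mouse 6, and 27 without colon of mouse 5.

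The tissue differences depended on sex or cage for 5 genes by edgeR's interaction test. Olfr1039 (ENSMUSG00000075204.4), an olfactory receptor, had 5060 CPM in F and 1979 in M in bone marrow, 289 and 142 in colon and 79.2 and 527 in esophagus (adjusted p = 0.00101). Gm19087 (ENSMUSG00000100595.2) was at 1644 and 484 CPM in bone marrow and 0 and 20.3 in esophagus (0.0338), and Man2c1 (ENSMUSG00000032295.16), an alpha-mannosidase, at 4938 and 941 in bone marrow and 43.9 and 163 in esophagus (0.0338). The last pair, Fth1 (ENSMUSG00000024661.8), ferritin heavy chain, at 77.5 and 1086 CPM in F and M colon (0.0440), and Rpl38 (ENSMUSG00000057322.13), a ribosomal protein, at 0 and 286 (0.0440), were outside the rule and chosen after their values were seen. In edgeR with a mouse block 0 genes were called, with adjusted p of 0.986, 0.983, 0.521, 1.0 and 0.879. Without any 1 esophagus library the count was 0, without each bone marrow library 1, and without colon of mouse 7 it was 10. It was 1 by library size alone.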

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

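The tests of the X-linked ratio, the granule and myeloid marker densities, the odds of a run and the markers of dendritic cells, macrophages and B cells were chosen only after the result was seen; those of run length without a long run, of the RNA share and of other splits were planned.

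Counts per kilobase of smell receptor genes were as high as those of other coding genes in every library, by 1.25 to 2.12 times. This ratio and the X-linked ratio leave out the 1% of genes with the most counts in each library. The tables argue against eosinophil granule transcripts as the main content. The median granule gene had at most 0.902 times the counts per kilobase of the receptor genes in any of the 15 libraries. Eosinophils with few granule transcripts are not covered by that test. The median gene of the eosinophil surface list, also looked at afterwards, had at most 0.886 times. Pooled, that list was at 0.430 to 1.60 times in esophagus, 0.432 to 0.686 in colon and 11.9 to 32.8 in bone marrow. Itgam alone was at 158 to 448 times in bone marrow. Unspliced nuclear RNA as the main content is argued against by X-linked genes. Relative to autosomal coding genes they were 0.528 times as high in M as in F mice, where dosage-compensated RNA would give a ratio near 1. Genomic DNA in the libraries may be a source of much of the counts, since this ratio of 0.528 follows gene copies. No biological explanation was tested, since every group shows the pattern.

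The second pattern is the set of 87 genes higher in bone marrow than in esophagus or colon, which took 4.46% to 17.1% of bone marrow counts and at most 0.651% elsewhere. Of these genes 47 (54.0%) hold a purine or pyrimidine run of at least 50 bases, against 1092 of 10254 other tested genes (10.7%), an odds ratio of 9.86 (Fisher's exact test, two-sided p = 4.93e-23), so reads from such runs may be a source for those genes. For the 40 genes without one, shorter runs are argued against. Their median longest run differed by -0.5 bases from that of other genes without a long run (permutation p = 0.763). Runs were sought in GENCODE M21 transcripts, leaving out runs of mostly 1 base, so any others are not covered. RNA of neutrophils and granulocyte progenitors is argued against by their median marker alone. With granule genes, it reached 0.686 times the receptor density in the highest bone marrow library. S100a8 and S100a9 had 0 to 7 counts in bone marrow, at medians of 0.267 and 0.55 times that density. Their highest libraries lay above it, at 5.79 and 7.57 times, on at most 7 counts, so these 2 genes do not decide it. These markers do not cover other myeloid cells. Some genes, picked after their values were seen, lay above the receptor density in bone marrow, such as Tmsb4x (5.67 to 486 times) and Actb (2.90 to 8.35 times). RNA of other myeloid cells thus stays open. A difference between tissue and bone marrow cells stays open and untested.

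The third pattern is the higher class II genes in esophagus than in colon. A larger share of RNA of every kind was tested on 63 ribosomal protein and oxidative phosphorylation genes, with a median log2 fold change of -0.085 (quartiles -0.97 and 0.85), which met a bound of 0.5 set before the result was seen, but the bound was wrong to ignore single libraries: without colon of mouse 8 the median was 1.11 and class II was at 3.0. Without the 4 libraries left out together these were 0.43 and 2.17, so an RNA share cannot be told apart from a class II difference. Markers of dendritic cells, macrophages or B cells (13 genes, the selection was for eosinophils) had a median of -0.10, but at 0.548 times the receptor density in esophagus they were too low to decide, with Ms4a1 and Trem2 the most abundant at 122 and 93.8 CPM in esophagus and 154 and 62.9 in colon, so such cells cannot be told apart either. A difference between esophageal and colonic eosinophils stays open and was not tested by any other measure.

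Other splits of the libraries show where chance can be excluded. For esophagus against bone marrow, 1 of 100 splits, the real one, gave as many as its 86 called genes. The highest other gave 60, with esophagus of mice 1, 3, 6 and 7 as one group. That excludes chance by this measure alone, since the splits ignore that mice 5 to 8 gave both tissues. For colon against bone marrow, 1 of 35 splits, the real one, gave as many as its 45 genes, with 0 in the highest other. These splits also ignore the pairing, since all libraries of both tissues came from mice 5 to 8. Swaps within mice are too few among them to exclude chance with the pairing kept. With mouse as a random block, many calls against bone marrow were lost, while a fixed block kept most calls of named genes. For esophagus against colon, 4 of 100 splits, the real one among them, gave as many as its 9 genes. These were drawn from 330 possible splits and ignore that mice 5 to 8 gave both tissues. So small a margin does not firmly exclude chance. With mouse as a fixed block 1 of the 9 calls was kept, H2-Ab1, and with a random block 1, Rn18s. The highest other split gave 345, with esophagus of mice 1, 3, 5 and 6 as one group, while the median of the other splits was 0. Why that split gave so many was not tested. The list counts do not exclude chance: 29 of 100 splits gave at least the 1 list called for esophagus against bone marrow (highest other 3), and 5 of 98 at least the 3 of esophagus against colon (highest other 4). For sex or cage, 1 of 35 splits of the mice gave as many as the 51 genes, which excludes chance by this measure alone. The splits that part mice 5 and 6 from mice 7 and 8, 6 with the real one, gave at least 38, with 47 in the highest other. The rest gave at most 42. The count thus does not set sex or cage apart from other differences between these pairs of mice. For the interaction, 10 of 34 splits gave at least 5 genes (highest other 18), so chance is not excluded.

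Within groups, 13 of 93 sets of 4 or 7 libraries had a library far from the others. For normally distributed values chance gives 1 in 20, or 4.65. Some sets held counts near 0, for which that value does not apply, so an excess is not shown. Mitochondrial counts were 7.516% in colon of mouse 8 (others 0.298% to 1.0%), and ribosomal protein counts 1.364% there (0.232% to 0.241%). Rn18s took 2.609% in esophagus of mouse 3 (0.323% to 1.26%). Colon of mouse 5 had 93.1 CPM of Itgam (20.4 to 22.9) and 223 of Trim12c (43.3 to 66.3). Esophagus of mouse 3 had 232 CPM of Itgam (39.8 to 120.0) and 10.1 of Amt (0 to 3.52). Esophagus of mouse 8 had 195 CPM of Cd274 (0 to 59.98), 18.8 of Bco1 (0 in the others) and 81.6 of Dppa2 (0 to 10.6). Bone marrow of mouse 6 had 402 CPM of Cd74 (85.5 to 135). Prg2 was at 49.3 CPM in esophagus of mouse 6 and 1.8 in colon of mouse 7, with 0 in the others of each tissue.

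The effect of tissue differed between F mice in cage 1 and M mice in cage 2 by edgeR's interaction test for Olfr1039 (adjusted p = 0.00101), Gm19087 (0.0338), Man2c1 (0.0338), Fth1 (0.0440) and Rpl38 (0.0440). With mouse as a block these 5 calls were lost (0.521 to 1.0), and the 10 of 34 splits above leave chance open.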

How the results depend on the processing

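Leaving out 4 libraries together and removing purine-run genes were chosen after seeing the data, and the other settings were planned. Called for esophagus against colon, the class II list kept its call and direction under all its alternatives and without any 1 library, as did Pecam1 for esophagus against bone marrow. Of 68 results for named genes, 49 were called, of which 1 was kept under all alternatives and 30 without any 1 library. Calls of named genes that were lost with mouse as a fixed or a random block are given in the report. Lists were not run under DESeq2, robust dispersion off, the 2-fold test or the random block. At this depth a count of 0 allows 4.90 to 35 CPM, and 11.4% to 14.4% of simulated 4-fold changes between tissues were found. Where a setting moved a result below, the cause was not tested, except that the 0.01 threshold and the 2-fold test lower a count by construction, and that removing purine-run genes takes away called genes that hold a run. These were 45 of the 84 lower genes in esophagus against bone marrow, 26 of the 45 in colon, 24 of the 42 in both, 25 of the 51 for sex or cage and 1 of the 5 for the interaction, and a further 2, 8, 7, 6 and 2 without a run lost their call.

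Genes higher in esophagus than in bone marrow (2) were 5 by library size, 8 with no filter, 8 with DESeq2, 1 with quality weights, 0 with the random replicate block, 4 in mice 5 to 8, 1 in the 2-fold test, 0 at the 0.01 threshold and 0 to 7 without 1 library. Lower genes (84) were 145 with no filter, 23 with quality weights, 39 without purine-run genes and 74 to 110 without 1 library.

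Genes higher in colon than in bone marrow (0) were 1 by library size, 12 with no filter, 5 with quality weights, 3 with robust off, 1 with the fixed replicate block, 3 in the fit of 2 tissues, 1 without the 4 libraries and 0 to 19 without 1 library. Lower genes (45) were 82 with DESeq2, 162 with quality weights, 79 with the fixed and 14 with the random replicate block, 136 in the fit of 2 tissues, 85 in mice 5 to 8, 27 at 0.01, 80 without the 4 libraries, 11 without purine-run genes and 42 to 74 without 1 library.

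Genes higher in esophagus than in colon (7) were 15 with no filter, 3 with the stricter filter, 15 with DESeq2, 4 with quality weights, 2 with robust off, 2 with the fixed and 1 with the random replicate block, 12 in the fit of 2 tissues, 1 in mice 5 to 8, 1 in the 2-fold test, 2 at 0.01, 4 without mitochondrial, ribosomal protein and hemoglobin genes, 0 without the 4 libraries and 1 to 14 without 1 library. Lower genes (2) were 1 with RLE, 82 with no filter, 0 with the stricter filter, 0 with DESeq2, 0 with quality weights, 4 with sex as a covariate, 4 in the fit of 2 tissues, 0 in the 2-fold test, 0 at 0.01, 1 without mitochondrial, ribosomal protein and hemoglobin genes, 0 without the 4 libraries, 4 without purine-run genes and 0 to 22 without 1 library.

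Genes lower in both tissues (42) were 65 with no filter, 67 with DESeq2, 22 with quality weights, 64 with robust off, 67 with the fixed and 12 with the random replicate block, 74 in mice 5 to 8, 26 at 0.01, 71 without the 4 libraries, 11 without purine-run genes and 40 to 69 without 1 library. Genes higher in both (0) stayed at 0 by edgeR, DESeq2 and quality weights, with 0 to 1 without 1 library.

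Lists called for esophagus against bone marrow (1) were 0 with RLE, upper-quartile and library size scaling, no filter, the 0.01 threshold and without the 4 libraries, 3 with the fixed replicate block and 0 to 2 without 1 library. Lists for colon against bone marrow (0) were 1 with quality weights, 3 with the fixed replicate block, 1 in the fit of 2 tissues and 0 to 1 without 1 library. Lists for esophagus against colon (3) were 1 with no filter, 1 at 0.01, 1 without the 4 libraries and 1 to 6 without 1 library.

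Genes called for sex or cage (51) were 29 with no filter, 3 in esophagus alone and 10 with no replicate block, both by edgeR in place of limma so that the tool changed too, 20 without purine-run genes and 21 to 73 without 1 library. Interaction genes (5) were 9 with RLE, 8 with upper-quartile scaling, 1 by library size, 3 with no filter, 0 with the stricter filter, 0 with the fixed replicate block, 0 in mice 5 to 8, 1 at 0.01, 0 without the 4 libraries, 2 without purine-run genes and 0 to 10 without 1 library. Of the named genes, 3 results reversed: the sex or cage differences of Trim12c, Itgam and Rsu1 were 0.53, 0.38 and 0.59 in esophagus alone. The cause of these was not tested.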

Other observations

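The genes below were chosen after their values were seen, and no test was run on them. Several transcripts of colon epithelium stood out in the colon library of mouse 8, the one with the high mitochondrial share. Pigr, which carries immunoglobulin A across epithelium, had 2132 counts there and 3 to 122 in the other colon libraries. Lgals4 had 404 counts (0 to 15 in the others), Agr2, of mucus-secreting cells, 384 (0 to 3), Krt8, a keratin of simple epithelium, 266 (1 to 2) and Zg16, a goblet cell lectin, 257 (2 to 8). Slc26a3, a chloride exchanger, had 148 counts (9 to 26), Cdh17, an intestinal cadherin, 117 (2 to 14) and Tfrc, the transferrin receptor, 192 (13 to 26). Of 22 genes listed for colon epithelium, 16 had a higher CPM in this library than in the other 3 colon libraries, 8 of them by over 3 times the next, and 6 did not, such as Phgr1 and Guca2a with 0 counts. The same 22 genes took 0.303% of its counts, and 0.0255% to 0.0323% in the other 3.

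In esophagus, Ly6d, found in squamous epithelium and B lineage cells, had 182 counts in the library of mouse 1 and 0 in the other 6, and Des, of muscle, had 67 in mouse 1 and 0 to 21 in the others. Krt18 had 32 counts in mouse 3 and 0 to 3 in the others. Xcr1, of dendritic cells, had 71 in mouse 6 and 0 to 17 in the others. The neutrophil genes S100a8 and S100a9 had 0 to 14 and 0 to 17 counts per esophagus library, 1 to 5 and 0 to 2 in the deeper colon libraries and 0 to 7 each in bone marrow. Relative to the counts per kilobase of smell receptor genes, their medians were 2.16 and 6.74 in esophagus, 0.281 and 0.505 in colon and 0.267 and 0.55 in bone marrow. Other neutrophil genes went the other way: Ngp, Ltf, Mpo and Csf3r had medians of 0 in esophagus and 0.156 to 0.615 in colon. Camp was at 0 in all 3 tissues. The median gene of the neutrophil list was at 0 in esophagus, 0.331 in colon and 0.372 in bone marrow.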
